A study of Mus musculus with 72 samples.

How the data were processed

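RNA was sequenced from the hypothalamus of adult B6 mice that carried either a knockout of 1 of 5 conserved noncoding elements, named E1 to E5 in the labels, or the wild type sequence. Mice were fed or had been deprived of food for 72 h with water available. The 72 libraries fall into 20 groups of 3 or 4, by element, feeding state and genotype. Per the labels, total RNA was purified with Qiagen RNeasy columns and libraries were made with an Ultra II DNA library kit; the strand of the reads is not stated there. The labels give neither the positions of the elements nor the genes that they were thought to control, and the deposited tables carry the name of the gene Fto.

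The deposited files hold 10 tables of raw counts per Ensembl gene, 1 for each element and feeding state, which the authors made with HISAT2, Bowtie2 and the mm10 genome; versions, and the tool that counted the reads, are not stated. The values are whole numbers and no normalization had been applied. In E1 and E3 the tables list 21749 genes, in E4 they list 52286 and in E2 and E5 55401. Mitochondrial genes are listed with 0 counts in all 10 tables. Every count column was matched to 1 library by its group and number, so 0 columns were left without a sample; in the E3 tables the column names begin with ctrl or 3CR, which were read as fed and fasted because the tables are named so. The authors also deposited edgeR results for 8 of the 10 genotype comparisons, as log2 fold changes of wild type over knockout with p values, adjusted p values and q values for protein-coding genes; these were used only for the side-by-side counts given among the other observations.

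Depth ranged from 5517552 to 39999368 counts per library. Intervals below carry 95% confidence and come from the fitted models. Symbols were taken from the reference annotation by Ensembl identifier, and coordinates of the locus from the same annotation. Levels of the locus genes and of genes named for interactions are CPM (library counts scaled to a common total) further scaled by the normalization factors of their fit; all other levels are CPM of the library total.

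Genotype was tested within each element and feeding state with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM normalization, genes kept by filterByExpr with a minimum count of 10 and a minimum total of 15), knockout against wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Knockout and wild type of a comparison shared a sequencing batch. Fasting was tested in the wild types of E1 and E3, with the element as a covariate, because only there did fed and fasted libraries share a batch; in E2, E4 and E5 feeding state and batch coincided. The interaction of genotype and feeding was tested within each element, and the genes around Fto were also tested over both feeding states with feeding as a covariate. Sex was not a covariate, since by Ddx3y it coincided with the element.

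A total of 36 gene lists for pathways, cell types, neighbouring brain regions and other tissues were fixed with the tests, the alternatives and the rule for named genes before the data were examined. Lists of at least 5 measured genes were tested with camera from limma 3.58.1, with the correlation between genes preset to 0.01. The same test with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, served as alternatives. Lists for fat, skeletal muscle and liver, a set of 10 genes abundant in a single E4 library, and a list of ribosomal RNA models were added after single libraries had been looked at. From the liver list, Ttr and Cyp2e1 were removed after their values had been seen, because choroid plexus and fat also express them.

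Genes were named by these rules. In genotype comparisons they were Fto, Rpgrip1l, Irx3, Irx5 and Irx6, other called genes near Fto, and up to 10 called genes per direction by p. In the fasting comparison they were the 12 called genes per direction with the largest fold change among those with a mean log2 CPM of at least 1 and the same direction in E1 and E3, plus up to 6 called members of the lists of feeding peptides and of glucocorticoid targets. Lists past the test were illustrated with up to 4 called members per direction, and interactions with the 5 genes of smallest p. Predicted gene models were left out, and the results of some genes that these rules name are not reported here. Because genotype comparisons called no genes, the genes of smallest p in each (up to 4 per direction, mean log2 CPM of at least 1) were added after their values had been seen.

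The alternatives fixed in advance were RLE normalization, DESeq2 1.42.0, no filter on low counts, both feeding states in one model, each library left out in turn, and a block for the replicate number. The edgeR likelihood ratio test, genes common to all tables, fits without libraries that held transcripts of other tissues, and fits with each library's trend on GC content or transcript length taken out (a spline with 5 degrees of freedom) were added later. Other splits of the same libraries were fitted in the same way, all of them or 100 drawn at random. Replicate numbers were checked for pairing in the 5 cases where both groups share them: in none did the residuals of libraries with the same number correlate consistently (from -0.262 to 0.392), so the block is given only as an alternative. Among 96 pairs of replicate libraries, 0 were identical.

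The tests were also run on simulated counts with known changes in 200 genes. Of the genes changed 2-fold, the share recovered in genotype comparisons was between 29.9% (E2 fasted) and 94% (E1 fed); it was 91% in the fasting comparison and between 25.4% and 76.1% for interactions. False calls were up to 18 of 145 calls (fasted E3), 20 of 219 (fed E1), 15 of 177 (fed E3) and 15 of 179 (fed E5) in genotype comparisons, more than the 5% aimed at, with 8 of 200 for fasting and 8 of 114 for the E3 interaction. A list raised in the simulation passed in 16 of 16 comparisons and an unchanged list in 0. Simulated genes varied independently of each other. The run therefore does not show how the list test behaves when the genes of a list are correlated. Differences that many genes of a library share, as with uneven dissection, were not simulated either. The shares recovered may thus be higher than in the real libraries. For genes changed 1.5-fold they were between 2.99% (E2 fasted) and 77.6% (E1 fed) in genotype comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.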

Results

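The data are total RNA sequencing counts from mouse hypothalamus, in 72 libraries from 5 lines in which 1 conserved noncoding element (E1 to E5) was knocked out, each with its own wild types. Every line was sampled fed and after 72 h without food. Groups held 4 mice, except 3 in each of the 4 E3 groups, in fasted E2 wild types and knockouts, in fasted E4 knockouts and in fasted E1 wild types. Depth was 14931889 to 19816134 counts per library in E1, 23322124 to 39999368 in E2, 14911351 to 23619033 in E3, 5517552 to 33981500 in E4 and 18614527 to 30330400 in E5. The Y-linked gene Ddx3y was at 69.8 to 136 CPM in the E3 libraries and at 0.298 CPM or less in all others. Xist was at 0 in every E2, E4 and E5 library and is not listed for E1 and E3, so sex was read from Ddx3y alone; by that gene it coincided with the element and did not differ between knockout and wild type.

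The first question was whether an element's knockout changed the genes around Fto, the locus that the deposited tables name. Fto encodes an RNA demethylase (ENSMUSG00000055932, mm10 chromosome 8, 91313525 to 91668439, plus strand). It starts beside Rpgrip1l, a gene of the primary cilium (91217030 to 91313262, minus strand). The homeobox genes Irx3 (91798525 to 91802067), Irx5 (92357625 to 92376286) and Irx6 (92674288 to 92680956) follow on the same chromosome. Fto was abundant in every group, at group means between 249 and 402 scaled CPM. In E1 it was at 392 ± 17.9 in fed wild types against 402 ± 12.5 in fed knockouts (SD, n = 4 each), and at 378 ± 30.6 (n = 3) against 351 ± 13.8 (n = 4) when fasted. E2 gave 339 ± 16.3 against 327 ± 41.9 fed (n = 4 each) and 360 ± 49.3 against 328 ± 15.4 fasted (n = 3 each). E3 gave 317 ± 21.3 in fed wild types, with fed knockouts at log2 -0.18 (SE 0.09), and 249 ± 5.32 against 284 ± 8.96 fasted (n = 3 each). E4 gave 357 ± 20.9 against 330 ± 17.5 fed (n = 4 each) and 315 ± 19 (n = 4) against 343 ± 13.7 (n = 3) fasted. E5 gave 354 ± 30 against 349 ± 49 fed and 299 ± 35.6 against 322 ± 19.3 fasted (n = 4 each).

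None of these differences in Fto passed the test. Over both feeding states the knockout changed Fto by -0.03 (SE 0.05) on the log2 scale in E1, -0.08 (0.08) in E2, 0.01 (0.08) in E3, -0.01 (0.07) in E4 and 0.05 (0.07) in E5. The 95% intervals of these estimates ran from -8.6 to 5.0% in E1, -15.7 to 6.6% in E2, -11.1 to 14% in E3, -9.6 to 9.5% in E4 and -7.1 to 14.7% in E5. The Irx genes were low and their intervals wide. Irx3 in fed E2 knockouts was at 1.81 ± 0.201 scaled CPM against 2.97 ± 0.714 in wild types (n = 4 each, log2 -0.71, SE 0.22, edgeR adjusted p 0.866, 0.242 adjusted over the list alone). Irx5 was lower in fed E3 knockouts (log2 -1.10, SE 0.43, edgeR adjusted p 0.478, list alone 0.197) and higher in fasted E5 knockouts (0.46, SE 0.19; 0.674, list alone 0.195). In fasted E4 knockouts Rpgrip1l was at 0.30 (SE 0.12) and Irx3 at -0.62 (SE 0.28), each with an adjusted p of 0.351 over the list alone. Several of these estimates moved with single libraries: Irx5 in fed E3 was at -1.68 without knockout 3 and -0.70 without knockout 2, and Rpgrip1l in fasted E4 at 0.17 without knockout 1, the library led by 10 genes, and 0.45 without knockout 2. The 95% intervals of Irx6 included 0 in each of the 10 genotype comparisons, the largest estimate being 0.67 (SE 0.46) in fasted E3 knockouts (0.39 without wild type 1). Of 27 to 29 measured genes on the fixed list of the locus, edgeR called 0 in each of the 10 genotype comparisons and over both feeding states, over all genes and adjusted over the list alone; between 0 and 5 of them per comparison had an unadjusted p under 0.05, and DESeq2 also called 0. Among the 14 to 24 measured genes that start within 2 Mb of Fto, 0 were called. The smallest adjusted p over the list alone was 0.078, for Herpud1, a gene of the endoplasmic reticulum stress response, in fasted E5 (log2 -0.28).

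**Figure D1:**
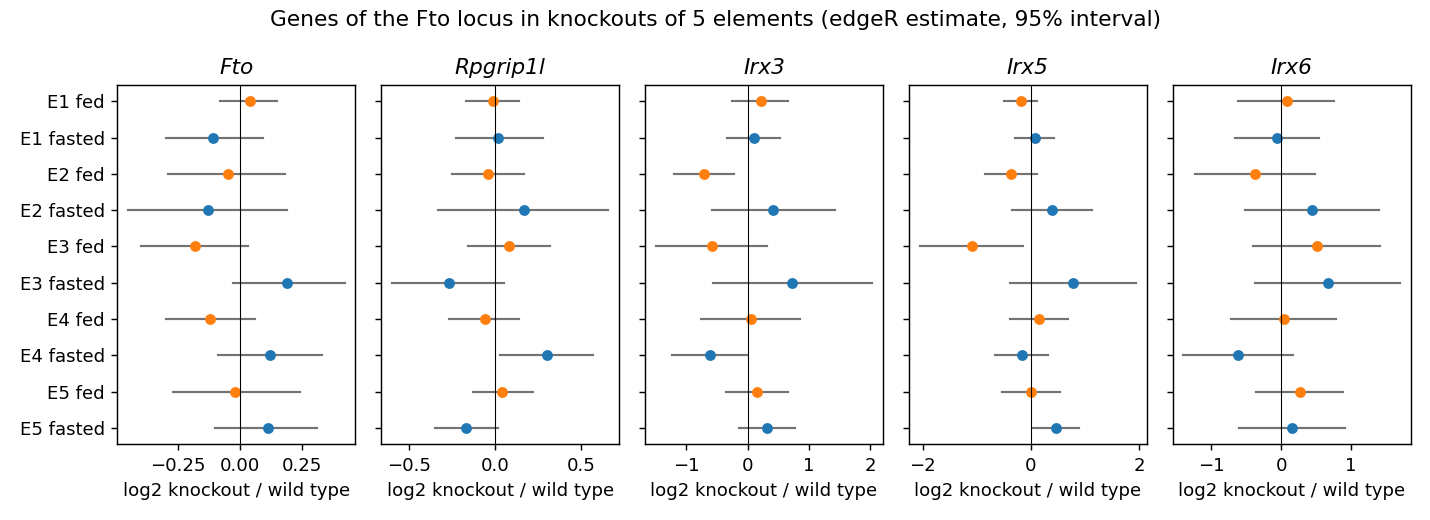
Estimated log2 difference of knockout over wild type (horizontal axis) for 5 genes of the Fto locus in each genotype comparison (rows), with orange points for fed and blue points for fasted mice and bars for 95% intervals; each panel has its own scale. The estimates for Fto lie between -0.18 and 0.19.

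Across the genome the question for each element was which genes differed between knockout and wild type in the same feeding state. Because edgeR called no gene, those named for each element are among the ones of smallest p, picked after their values were seen. Fed E1 knockouts had the collagen gene Col1a1 at 19.8 ± 4.37 against 33.3 ± 7.18 CPM (n = 4 each, log2 -0.75, SE 0.16) and Slc17a7, a vesicular glutamate transporter, at 3.60 ± 1.54 against 12.9 ± 9.84 (-1.82, SE 0.42). Slc17a7 was at 27.6 CPM in fed wild type 3 and at 6.71 to 8.75 in the other 3 wild types, and transcripts of the thalamus list summed to 1719 in that library, against 826 to 1156 in the other fed E1 libraries. Socs2, an inhibitor of cytokine signalling, was at 22.4 ± 4.12 against 14.9 ± 2.55 (0.57, SE 0.14). Fasted E1 knockouts had Arhgap29, a GTPase-activating protein, at 24.5 ± 0.972 (n = 4) against 17.1 ± 1.04 (n = 3; 0.53, SE 0.09) and the protease gene Tll1 at 13.1 ± 1.97 against 7.22 ± 0.838 (0.88, SE 0.16). Their edgeR adjusted p was 0.953 fed and 0.954 fasted. edgeR called 0 of 14734 genes fed (715 with an unadjusted p under 0.05; DESeq2 0) and 0 of 14947 fasted (583; DESeq2 2, Arhgap29 and Tll1). Without fed wild type 2, a library with skeletal muscle transcripts at 376.1 summed CPM against 14.3 to 20.2 in the other fed wild types, 1 gene was called. The added list of skeletal muscle genes had a median log2 of -3.43 in fed knockouts (camera adjusted p 0.00748; adjusted p = 0.811 with an estimated correlation).

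In E2, fasted knockouts had lower levels of the transcripts of anterior pituitary cells than their wild types. Growth hormone (Gh) was at 600 to 5930 CPM in the 3 fasted wild types and at 0 to 16.7 in the 3 knockouts, and prolactin (Prl) at 662 to 5630 against 0 to 9.31. All 10 measured genes of the pituitary list were lower in knockouts (median log2 -5.24, camera adjusted p 3.65e-12; adjusted p = 0.274 with an estimated correlation). Among them were Fshb, the beta chain of follicle-stimulating hormone (-7.53, SE 1.17), Ghrhr, the receptor for growth hormone-releasing hormone (-7.32, SE 1.15), and Pou1f1, a pituitary transcription factor (-6.98, SE 1.16). All 24 genes of cholesterol synthesis had positive estimates in fasted knockouts (median 0.26, camera adjusted p 5.64e-13; adjusted p = 0.231 with an estimated correlation), with the sterol sensor Insig1 at 101 ± 3.91 against 65.5 ± 4.43 CPM (n = 3 each; 0.60, SE 0.10). None of these genes passed edgeR on its own (adjusted p 0.66): it called 0 of 20243 genes fasted (1512 with an unadjusted p under 0.05), where DESeq2 called 104, 12 higher and 92 lower, among them Fshb, Ghrhr, Pou1f1 and Insig1. Without fasted wild type 3 edgeR called 772 genes, and without fasted wild type 1 it called 71. Fed E2 knockouts had Cck, the gene of cholecystokinin, at 11.4 ± 4.82 against 5.45 ± 0.515 CPM (n = 4 each; 1.09, SE 0.27, edgeR adjusted p 0.866), and 0 of 18723 genes were called by edgeR (656 with an unadjusted p under 0.05) or DESeq2 (0). Fat transcripts summed to 12490 CPM in fed knockout 3 and to 27.5 or less in the other fed knockouts. Liver transcripts summed to 17.6, 1.75 and 110 CPM in the fasted knockouts and to 2.64, 5.29 and 5.0 in the fasted wild types.

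In E3, fed knockouts had lower levels of several endothelial genes. Flt1, a receptor for vascular endothelial growth factor, was at 26.0 ± 0.79 against 54.1 ± 8.72 CPM (n = 3 each, log2 -1.08, SE 0.13), Adgrl4 at 11.2 ± 0.307 against 23.9 ± 4.41 (-1.13, SE 0.15) and Ptprb at 23.1 ± 0.182 against 35.7 ± 3.75 (-0.65, SE 0.10). The motor protein gene Myo5b was at 46.3 ± 5.76 against 25 ± 2.46 (0.87, SE 0.12) and the sodium-calcium exchanger Slc8a2 at 105 ± 4.52 against 68.1 ± 4.09 (0.61, SE 0.08). Their edgeR adjusted p lay between 0.158 and 0.191. Drd1 was read as a sign of striatum. It was at 36.9, 55.8 and 12.3 CPM in fed knockouts and at 12.6, 4.71 and 13.7 in fed wild types. Whether uneven dissection lies behind the differences in fed E3 was not tested. All 15 measured endothelial genes had negative estimates (median -0.51, camera adjusted p 2.87e-11; adjusted p = 0.639 with an estimated correlation), as did all 5 of red blood cells (median -3.15; 3.2e-05; adjusted p = 0.863 with an estimated correlation). In fasted E3 knockouts Ropn1l, a gene of cilia and sperm tails, was at 15.4 ± 0.319 against 28.7 ± 3.13 (n = 3 each; -0.97, SE 0.14) and Spsb1, an adaptor of ubiquitin ligases, at 31.8 ± 2.11 against 18.6 ± 1.52 (0.70, SE 0.12), both at an adjusted p of 0.146. The list of glucocorticoid and fasting genes had 21 of 23 positive estimates there (median 0.44, camera adjusted p 1.14e-05; adjusted p = 0.687 with an estimated correlation). edgeR called 0 of 14602 genes fed (1422 with an unadjusted p under 0.05; DESeq2 107, 56 higher and 51 lower) and 0 of 14590 fasted (2546; DESeq2 527, 114 higher and 413 lower). With both feeding states in one model, 605 genes were called for fasted E3; without fed knockout 3, a library with choroid plexus transcripts, 1 was called for fed E3.

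In E4, fasted knockouts had Avp, the gene of vasopressin, at 61.9 ± 42.4 (n = 3) against 236 ± 62.3 CPM (n = 4, log2 -1.75, SE 0.29) and the astrocyte filament gene Gfap at 80.1 ± 9.69 against 194 ± 53.8 (-1.02, SE 0.21). Mat1a, a liver enzyme of methionine metabolism, was at 4.01 ± 3.58 against 0.282 ± 0.336 (4.11, SE 0.69), and the liver list summed to 39.2, 143 and 4.96 CPM in the 3 knockouts and to between 1.80 and 11.9 in the 4 wild types. The list of meningeal and vascular fibroblasts had a median of -1.53 (camera adjusted p 1.18e-06; adjusted p = 0.397 with an estimated correlation). In fasted knockout 1, with 5517552 counts, the 10 most abundant genes took 36.3% of counts. That share lowers the CPM of all other genes in this library, where Avp was at 28.6, against 110 and 47.3 in knockouts 2 and 3. Avp also varied widely within fed groups, at 34.9 to 140 CPM in wild types and 90.8 to 322 in knockouts. Fed E4 knockouts had Rgs5, a pericyte gene, at 31 ± 1.98 against 46.4 ± 2.45 (n = 4 each; -0.61, SE 0.09) and Carmil3 at 64 ± 1.05 against 83.1 ± 1.94 (-0.41, SE 0.07). None passed edgeR, with adjusted p values of 0.419 fasted and 0.787 fed. It called 0 of 17929 genes fasted (1684 with an unadjusted p under 0.05; DESeq2 18, 4 higher and 14 lower) and 0 of 18430 fed (964; DESeq2 4, all lower, among them Rgs5 and Carmil3). Without fasted knockout 3, whose pituitary transcripts summed to 6441 CPM, 23 genes were called; without fasted knockout 2, 1; and with no filter on low counts, 169.

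In E5, fasted knockouts had lower estimates for all 69 measured ribosomal protein genes (median log2 -0.25, camera adjusted p 4.82e-35; adjusted p = 0.492 with an estimated correlation). Rps27 was at 78.6 ± 3.65 against 105 ± 8.22 CPM (n = 4 each; -0.42, SE 0.07) and Fos, an immediate early gene of neuronal activity, at 6.34 ± 0.565 against 10.5 ± 1.59 (-0.74, SE 0.14). Fed E5 knockouts had Tsc22d3, a glucocorticoid target, at 71.5 ± 3.17 against 54.7 ± 2.57 (0.38, SE 0.07) and the chaperone Dnajb1 at 36.1 ± 3.6 against 27.2 ± 2.5 (0.40, SE 0.08; n = 4 each). None of these passed edgeR (adjusted p 0.667 fasted and 1 fed). It called 0 of 18569 genes fasted (1360 with an unadjusted p under 0.05; DESeq2 17, 3 higher and 14 lower, Rps27 and Fos among them) and 0 of 18206 fed (2.82% of them with an unadjusted p under 0.05; DESeq2 1, Tsc22d3). Pituitary transcripts summed to 18930 CPM in fasted knockout 3 and 4551 in fasted wild type 3, and choroid plexus transcripts to 3360 in fasted wild type 1; without these 3 libraries edgeR called 0.

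The lists passed camera often in genotype comparisons: 9 to 17 of the 32 to 34 tested in each. With an estimated correlation 0 passed in any of the 10, the smallest adjusted p being 0.231 (E2 fasted), and fry passed 0. The ribosomal protein list, also read as a sign of RNA preparation, passed camera in 9 comparisons. Its median was positive in fasted E1, fed and fasted E2, fed E3 and fed E4, and negative in fed E1 and in fasted E3, E4 and E5.

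**Figure D2:**
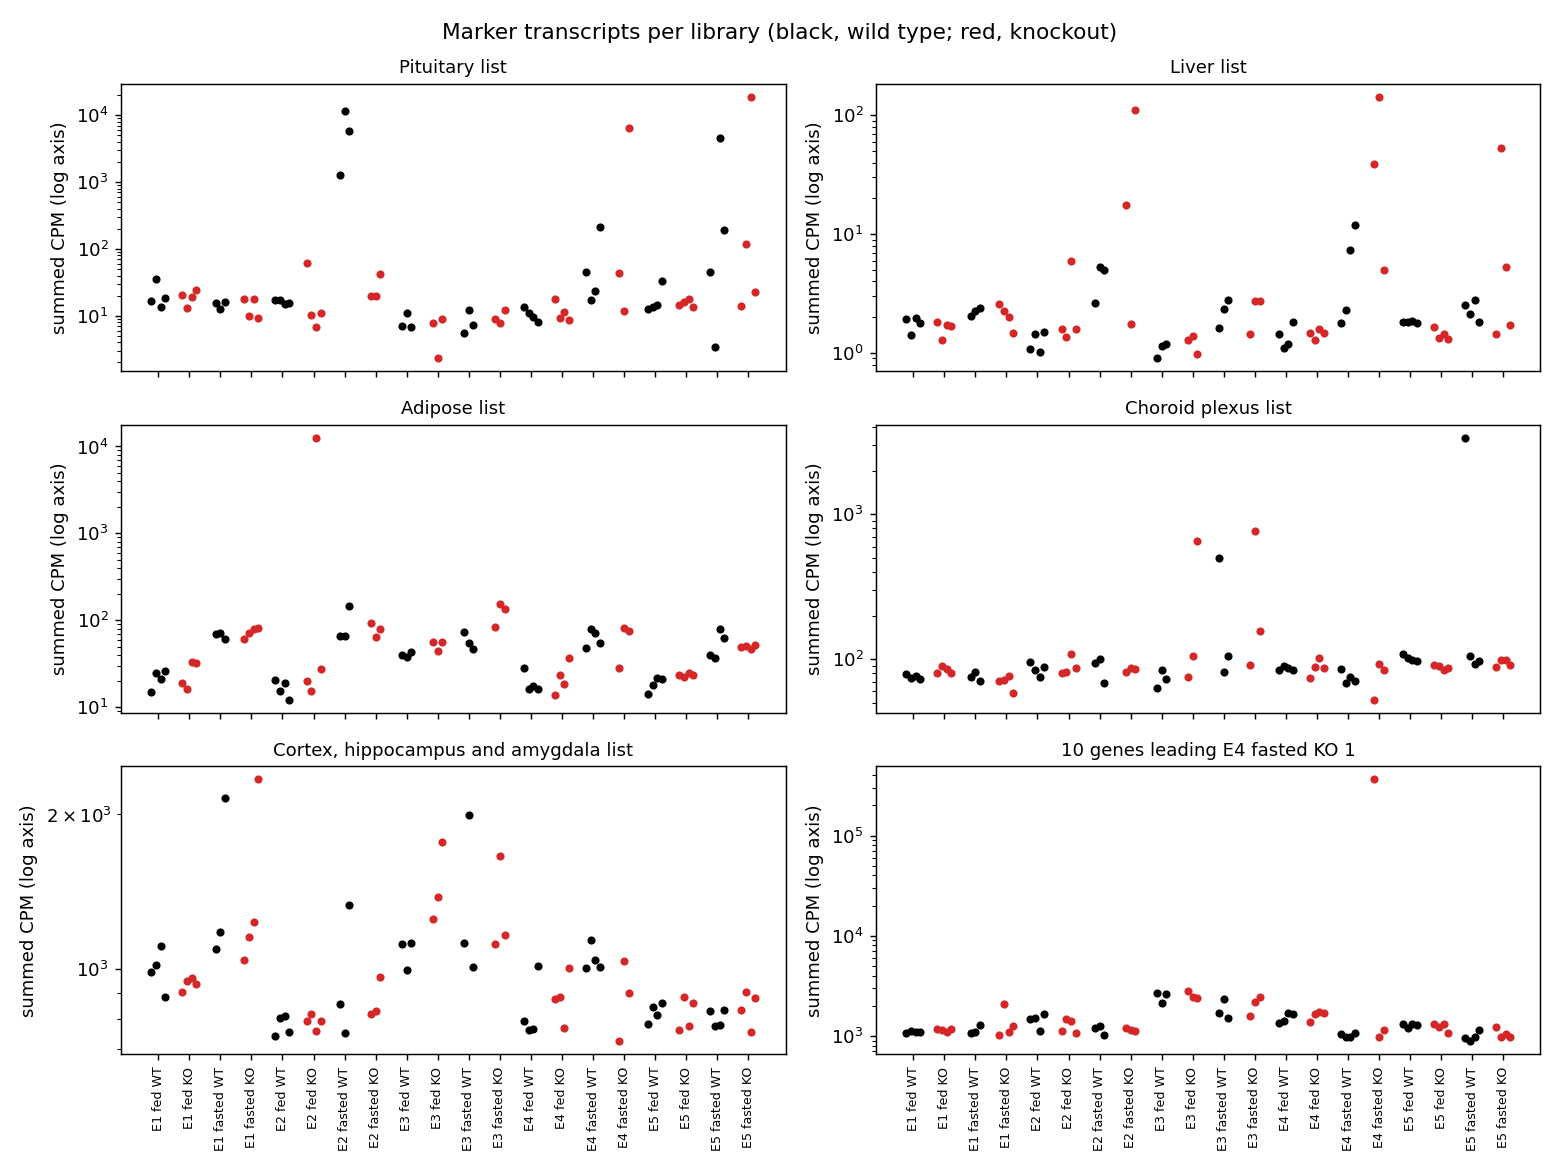
Summed CPM (vertical log axis) of 6 sets of marker genes in each of the 72 libraries (points; black, wild type; red, knockout), by group along the horizontal axis. Pituitary transcripts stand out in the 3 fasted E2 wild types (1288 to 11730), fasted E5 knockout 3 (18930), fasted E4 knockout 3 (6441) and fasted E5 wild type 3 (4551), and the 10 genes that lead fasted E4 knockout 1 stand out in that library alone.

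Whether a knockout acted differently in fed and fasted mice was tested as an interaction. In E3, 202 of 15033 genes were called: for 73 the knockout estimate was higher fasted than fed, and for 129 it was lower. Gpm6a, a neuronal membrane glycoprotein, was at 672 ± 14 scaled CPM in fed and 1280 ± 11.9 in fasted wild types, and at 812 ± 39.2 and 803 ± 63.2 in knockouts (n = 3 each, interaction -0.95, SE 0.13, edgeR adjusted p 0.0255). Spcs3, a subunit of signal peptidase, went from 37.0 ± 0.679 to 64 ± 3.82 in wild types and from 46.2 ± 2.01 to 43.1 ± 3.07 in knockouts (-0.89, SE 0.12; 0.0255). Zfp40, a zinc finger gene (-1.13, SE 0.15; 0.0255), and Ropn1l (-1.21, SE 0.18; 0.0357) followed the same pattern. Spsb1 went from 21.7 ± 1.21 to 19 ± 1.29 in wild types and from 16.2 ± 2.29 to 31.2 ± 2.71 in knockouts (1.13, SE 0.17; 0.0357). DESeq2 called 1104 genes and 3066 had an unadjusted p under 0.05. Fto had an estimate of 0.38 (SE 0.13, edgeR adjusted p 0.119, 0.0937 adjusted over the list alone), which did not pass; DESeq2 called 2 genes of the locus list.

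The E3 interaction calls differed in base composition. The 73 genes had a median transcript GC content of 54.3% and the 129 genes one of 39.8%, against 49.6% for all genes. The log2 level of GC-rich minus GC-poor transcripts was taken relative to the mean over all E3 libraries. On that scale fasted E3 wild types were at -0.50, -0.05 and -0.39 and fasted knockouts at 0.05, 0.01 and 0.39. With each library's GC trend taken out, 0 genes were called (smallest edgeR adjusted p 0.0847), and the median absolute log2 of the 202 genes went from 0.775 (median SE 0.157) to 0.491 (0.145). The count, more than the estimates, changed with single libraries. It was 697 without fasted wild type 2, 252 without fasted knockout 1, 183 without fed wild type 1, 29 without fasted knockout 3 and 0 without any 1 of the other 8; it was 12 with a replicate block. In the 8 fits with 0 calls the median absolute log2 of the 202 genes stayed between 0.743 and 0.808, and with the block it was 0.77. Without the 3 libraries that held choroid plexus transcripts (fed knockout 3 at 657 summed CPM, fasted knockout 2 at 769, fasted wild type 1 at 497) the count was also 0. There the 202 genes kept their direction and a median absolute log2 of 0.75 (median SE 0.185). In all these fits the 202 genes were likely to keep direction and size, since they were picked in a fit that held the same libraries. The other interactions called 0 genes by edgeR: E1 of 15222 (1233 with an unadjusted p under 0.05; DESeq2 0), E2 of 20452 (1320; DESeq2 22), E4 of 19393 (2168; DESeq2 2) and E5 of 19319 (1150; DESeq2 2). Without fasted wild type 1, E2 gave 28, and without fasted knockout 2, E4 gave 1.

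**Figure D3:**
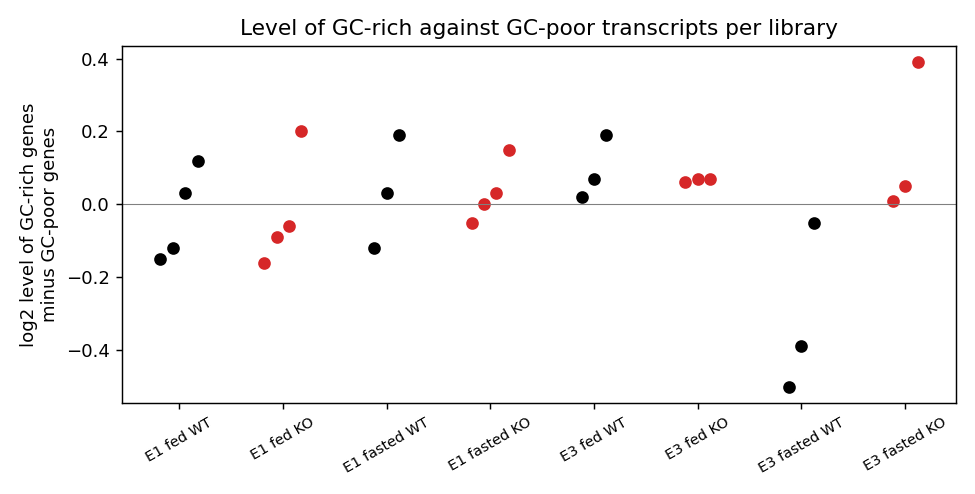
Mean log2 level of GC-rich transcripts minus that of GC-poor transcripts (vertical axis) in each E1 and E3 library (points; black, wild type; red, knockout), by group along the horizontal axis. Values are centred on the mean over the libraries of each element, so E1 and E3 have separate zero points. The 3 fasted E3 wild types lie between -0.50 and -0.05 and the 3 fasted E3 knockouts between 0.01 and 0.39.

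The elements were compared with each other by the genes called in more than 1 of them. With 0 called genes per genotype comparison, also at an adjusted p under 0.1, no gene could be shared in the 20 pairs of comparisons within a feeding state. Genes with an unadjusted p under 0.05 in both numbered 187 in fed E3 and E4 (72.6 by chance if genes were independent), 183 of them in the same direction, and 285 in fasted E3 and E5 (182.5), 270 in the same direction. In fasted E2 and E5 they numbered 193 (97.7), with 4 in the same direction, and in fasted E2 and E3 260 (181.2), with 15. Pearson correlations of the log2 fold changes across genes lay between -0.33 and 0.33; genes are not independent replicates. Drd1, read as a sign of striatum, was higher in some fed knockouts of E3, as given above, and of E4. In E4 it was at 5.55, 25.7, 5.23 and 35.8 CPM in fed knockouts and at 5.27, 4.20, 5.36 and 15.5 in wild types. Whether uneven dissection lies behind the direction shared by fed E3 and E4 was not tested. Within an element, fed and fasted knockout effects correlated across genes at -0.17 in E1, -0.09 in E2, -0.18 in E3, -0.19 in E4 and -0.15 in E5.

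Fasting was examined as the background on which the elements were studied, in the wild types of E1 (4 fed, 3 fasted) and E3 (3 and 3). It raised Npy, the appetite-promoting neuropeptide Y, 3.08-fold (log2 1.62, SE 0.16, edgeR adjusted p 0.000504), from 6.87 ± 1.18 to 23.6 ± 7.39 CPM in E1 and from 8.63 ± 1.33 to 23.6 ± 6.81 in E3; all 6 fasted wild types lay above the fed mean of their element. Pomc, the precursor of appetite-restraining melanocortins, fell by 0.94 on the log2 scale (SE 0.18; 0.00838), from 23.1 ± 3.03 to 9.66 ± 2.36 CPM in E1 and from 5.78 ± 0.58 to 4.12 ± 1.3 in E3. In E1 alone it was at -1.28 (edgeR adjusted p 0.00563), and in E3 alone it did not pass (-0.45, edgeR adjusted p 0.251). Ghsr, the ghrelin receptor (0.59, SE 0.17), and Cnr1, the cannabinoid receptor (0.42, SE 0.11), also rose. In E1 alone Cnr1 was at 0.14 (edgeR adjusted p 0.313), against 0.75 (0.00892) in E3 alone, and Ghsr passed in neither (0.60 in each). In a fit of the knockouts of both lines together Cnr1 was at -0.16 (0.03 in E1 and -0.36 in E3, none past the test). Leaving out 1 library, Ghsr stayed called in 5 of 13 fits and Cnr1 in 9, with estimates from 0.47 to 0.68 and from 0.33 to 0.47. Agrp, the other peptide of the hunger neurons, did not pass (-0.45, SE 0.14, edgeR adjusted p 0.0583), nor did Pmch (0.67, 0.136), Cartpt (0.13, 0.759), Hcrt (-0.03, 0.9) or Fto (-0.20, SE 0.07; 0.0804). In wild types of a single line Cartpt fell in E1 (-0.58, edgeR adjusted p 0.016) and rose in E3 (0.99, 0.0295). Pmch passed in E3 (1.67, 0.00162) and not in E1 (-0.23). Fto passed in E3 (-0.33, 0.0448) and not in E1 (-0.07). Agrp passed in neither, at -0.52 in E1 and -0.35 in E3. The lines also differed in batch, in sex by Ddx3y, and in the level of some peptides. In fed wild types Hcrt was at 63.4 CPM in E1 and 19.6 in E3, while Agrp was at 7.86 and 6.15. What lies behind the differences between the lines was not tested. In knockouts Agrp and Fto passed in E1 (-0.76, 0.00211 and -0.21, 0.0198) and not in E3 (0.18 and 0.03). In the joint fit of wild types, 3 of 21 measured orexigenic genes rose, 0 fell and 18 did not pass (5 adjusted over the list alone). Of 20 anorexigenic genes 1 fell.

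Targets of glucocorticoids and fasting rose in 14 of 22 measured genes and 0 fell (17 adjusted over the list alone, camera adjusted p 1.31e-13; adjusted p = 0.166 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose 3.41-fold (log2 1.77, SE 0.19, edgeR adjusted p 0.000504), and Arrdc2 2.37-fold (1.25, SE 0.15). Fkbp5, which restrains the glucocorticoid receptor (0.89, SE 0.10), the kinase Sgk1 (0.83, SE 0.10), the metal-binding protein Mt1 (1.02, SE 0.12) and Hif3a (0.93, SE 0.13) rose as well. Among 7 measured genes that low body temperature induces, 4 rose: the RNA-binding proteins Rbm3 (1.03, SE 0.13) and Cirbp (0.62, SE 0.14), Uchl1 (0.41) and Clk4 (0.29), with a camera adjusted p of 1.87e-05 and an adjusted p = 0.241 with an estimated correlation. Ribosomal proteins rose in 64 of 69 cases (Rps18 0.54, Rps14 0.49, Rpl17 0.60, camera adjusted p 3.55e-35; adjusted p = 0.338 with an estimated correlation). Nuclear genes of the respiratory chain rose in 12 of 53 (Ndufb4 0.66, Ndufb9 0.50, Ndufa4 0.74, Uqcr10 0.48; 2.46e-11; adjusted p = 0.722 with an estimated correlation). In the lists of fatty acid use, Pdk4, which spares glucose (0.60, SE 0.14), rose, and 22 of 24 genes did not pass.

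**Figure D4:**
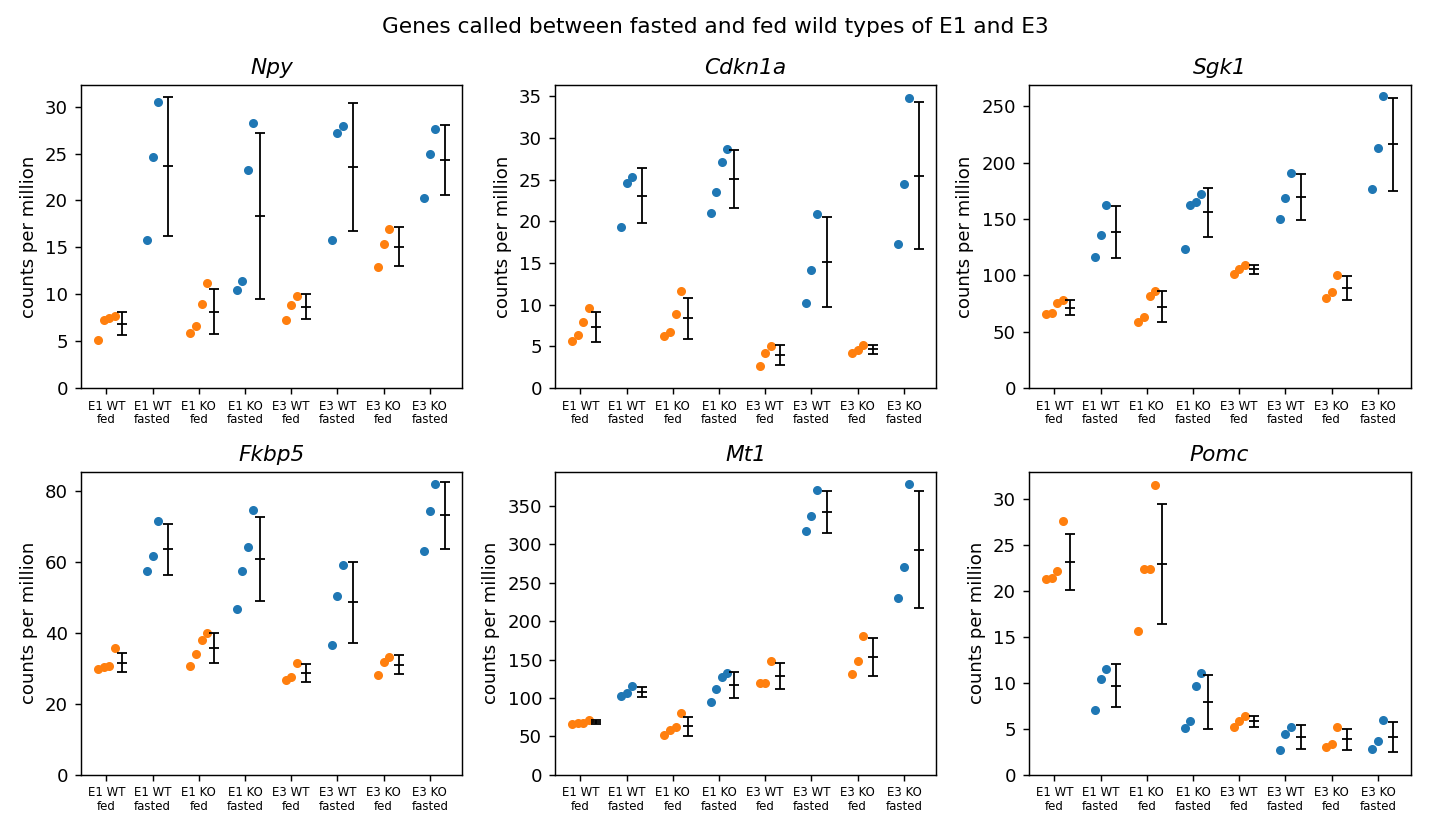
CPM (vertical axis) of 6 genes called between fasted and fed wild types, in E1 and E3 libraries of both genotypes (orange points, fed; blue points, fasted; bars, mean and SD of the group). Npy was at 6.87 fed and 23.6 fasted in E1 wild types.

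Red blood cell transcripts fell with fasting, in 5 of 7 measured genes (camera adjusted p 2.65e-06; adjusted p = 0.19 with an estimated correlation). Their lead members were Slc4a1, the red cell anion exchanger (-3.28, SE 0.43), and the globins Hba-a2 (-2.13, SE 0.46), Hba-a1 (-2.12, SE 0.47), Hbb-bt (-2.02, SE 0.38) and Hbb-bs (-1.97, SE 0.38). In knockouts Hba-a2 (-1.11) and Hbb-bs (-0.98) fell in E1, but in E3 Hbb-bs was at 0.54 (edgeR adjusted p 0.815) and over both lines at -0.71 (0.129). Where feeding coincided with the batch, Hbb-bs was higher fasted in E5, at 0.90 in wild types and 1.25 in knockouts, and did not pass in E2 or E4. Summed blood CPM was 468 to 1040 in fed and 114 to 409 in fasted E1 wild types, and 10.9 to 36.3 against 2.53 to 5.58 in E3. Of 15 endothelial genes 3 fell, Flt1 (-0.88), Emcn (-0.55) and Pltp (-0.34), with a camera adjusted p of 0.000244 and an adjusted p = 0.722 with an estimated correlation. Tie1, an endothelial receptor (-1.28, SE 0.32), belongs to no fixed list and was not called without fed E3 wild type 2 (-1.21) or fasted E1 wild type 1 (-1.19), nor in E1 alone (-0.67) or the knockouts of both lines together (-0.55). Transcripts of cortex, hippocampus and amygdala rose in 7 of 18 measured genes (camera adjusted p 0.00163; adjusted p = 0.722 with an estimated correlation), among them Slc17a7 (2.15, SE 0.60), Lamp5 (0.73, SE 0.18), Mef2c (0.49) and Nrn1 (0.44). Their spread was wide. Without fasted E1 wild type 3 Slc17a7 was at 1.34 (edgeR adjusted p 0.0514); it stayed called in 6 of the 13 fits that left out 1 library, and in E3 alone it was at 1.27 (0.202). It was at 103 ± 117 CPM in the 3 fasted E1 wild types, and the list summed to 2153 CPM in fasted E1 wild type 3 and 1995 in fasted E3 wild type 2, against 885 to 1182 in the other wild types of these lines.

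Other genes with large rises were the zinc transporter Slc30a3 (1.97, SE 0.60), the inner ear protein Otoa (1.76, SE 0.23), the integrin Itgad (1.69, SE 0.36), the potassium channel subunit Kcnv1 (1.56, SE 0.39), and the transcription factors Fezf2 (1.41, SE 0.43) and Bhlhe22 (1.24, SE 0.36). Epyc, a proteoglycan of the matrix (1.33, SE 0.38), and Klra2, a lectin-like receptor (1.21, SE 0.24), rose too. In a fit of the knockouts of both lines together Epyc was at -0.38 (not past the test), with 0.88 (edgeR adjusted p 0.0281) in E1 knockouts and -1.25 in E3 knockouts. Several of these calls rested on single libraries. Kcnv1 was not called without fed E3 wild type 2 (1.41) or 3 (1.53). Slc30a3 stayed called in 4 of the 13 fits that left out 1 library and was at 0.96 (edgeR adjusted p 0.205) without fasted E1 wild type 3. Bhlhe22 stayed called in 5, at 0.82 (0.0817) without fasted E3 wild type 2 and 0.90 without fasted E1 wild type 3. Fezf2 stayed called in 4, at 0.79 without fasted E3 wild type 2, and Epyc in 6, at 0.82 without fasted E3 wild type 1. Fasted E1 wild type 3 and fasted E3 wild type 2 are the libraries with high cortex transcripts. In the knockouts of both lines together Slc30a3 was at 1.53, Bhlhe22 at 0.53, Fezf2 at 0.30, Kcnv1 at 0.13 and Klra2 at 0.49, none past the test. In E1 knockouts alone Slc30a3 passed (2.67, edgeR adjusted p 0.00852), as did Slc17a7 (5.11, 0.000398) and Klra2 (0.92, 0.00574), while in E3 knockouts they were at 0.05, 0.25 and -0.04. The thalamus list summed to 1102 to 2311 CPM in fasted E1 knockouts and to 826 to 949 in fed ones. Whether uneven dissection lies behind the rises in E1 knockouts was not tested. In E3 alone Otoa (1.02), Itgad (0.72) and Klra2 (0.86) did not pass, in E1 alone Kcnv1 (1.01) and Fezf2 (0.49) did not, and Slc30a3, Bhlhe22 and Epyc passed in neither line alone. Further large falls were those of the poly(A) polymerase Tent5c (-1.70, SE 0.33), Ninj2 (-1.30, SE 0.15), Ccdc163 (-1.22, SE 0.20), the collagen Col7a1 (-1.17, SE 0.32), Insc (-1.16, SE 0.16), Mpp4 (-1.09, SE 0.27) and the antiviral gene Rsad2 (-1.08, SE 0.33). Of these, Rsad2 stayed called in 2 of the 13 fits, Col7a1 in 6 and Mpp4 in 11 (not without fed E3 wild type 2, -1.05, or fasted E1 wild type 1, -0.92), all with the same sign. In 1 line alone Col7a1 (-0.43) and Rsad2 (-0.44) did not pass in E1, nor Mpp4 (-0.63) in E3. In the knockouts of both lines together Tent5c was at -0.635 and Rsad2 at -0.47, neither past the test. The edgeR adjusted p values of these rising and falling genes lay between 0.000817 and 0.0494.

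The remaining fixed lists did not pass camera in the fasting comparison. Of the lists added later, the set of genes abundant in fasted E4 knockout 1 had a median of -0.24 in its 9 measured genes (camera adjusted p 0.0339; adjusted p = 0.811 with an estimated correlation), and skeletal muscle did not pass (0.429). The Fto locus list had 2 genes up and 1 down of 27 (Mt1, Herpud1 0.34, Gnao1 -0.24; 5 adjusted over the list alone). Neuroendocrine peptides had 2 of 21 up (Sst 0.58, Scg2 0.34), tanycyte genes 1 of 16 (Dio2, which activates thyroid hormone, 0.82), immediate early genes 2 of 22 down (Fos -0.62, Sik1 -0.29), and heat shock genes 1 of 20 up. Endoplasmic reticulum stress had 2 of 20 up, the clock list 1 of 17 up (Cry1 0.41), cholesterol synthesis 1 of 24 down, and glycolysis 1 up (Gapdh 0.35) and 1 down (Pfkfb3 -0.34) of 21. N6-methyladenosine factors had 1 of 17 down (Mettl16 -0.41), cilium and Hedgehog genes 3 of 28 down (Ift172 -0.34, Gli2 -0.44, Adcy3 -0.36), and interferon genes 1 of 21 down. Among cell types, astrocyte genes had 3 of 13 up (Agt 0.63, Gjb6 0.53, Slc1a3 0.30), while oligodendrocytes (1 of 16), their precursors (1 of 11) and microglia (1 of 14) each had a single gene down, and choroid plexus (1 of 12) and ependyma (1 of 16) a single gene up. Amino acid stress (22 genes), thalamus (16), striatum (14), hypothalamic regions (30) and meningeal fibroblasts (11) had 0 called; the last had a median of 0.49 although its test pointed down. Lists of mitochondrial, pituitary and sex genes had fewer than 5 measured genes and were not tested.

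In the wild types of E1 and E3 together, fasting changed 1637 of 14847 genes, 798 up and 839 down (edgeR; 4369 with an unadjusted p under 0.05; DESeq2 2444). The rising genes had a median transcript GC content of 46.9% and the falling genes one of 52%, a difference of -5.03 points against -0.945 to 0.866 in random sets. With each library's GC trend taken out 2034 genes were called, among them 1489 of the 1639 called by the same fit without it, and all 1639 kept their direction at 94.2% of the median size. E1 alone gave 784, E3 alone 2891, and the knockouts of the 2 lines 3007, where 1572 of the 1637 genes kept their direction and 837 were called. Leaving out 1 library gave 3217 without fasted E1 wild type 3, 1048 without fasted E3 wild type 3, 1002 without fed E1 wild type 2, 974 without fasted E3 wild type 1, 956 without fed E1 wild type 3, 748 without fasted E1 wild type 1, 673 without fed E3 wild type 2 and 668 without fed E3 wild type 3. Where feeding coincided with the batch, Npy was also higher fasted than fed in wild types, at log2 3.0 (SE 0.33) in E2, 2.21 (SE 0.39) in E4 and 2.54 (SE 0.26) in E5, against 1.75 in E1 and 1.5 in E3. Pomc was not lower in those lines: it was at 4.99 in E2, 0.61 in E4 and 2.39 in E5 wild types, lines in which some fasted libraries held pituitary transcripts; pituitary cells also express Pomc.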

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

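The test of the E4 gene set in the other knockouts and the test of pituitary tissue in E2 were chosen after their results had been seen, and so were the E3 fits with GC content or transcript length taken out, with a replicate block or without choroid plexus libraries; the counts over other splits were planned.

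In E3 the knockout effect differed between fed and fasted mice for 202 genes. Among 100 splits 1, the real one, reached that count (highest other 4), a share under 0.05. Chance is unlikely but not excluded: 1 in 100 is the smallest share these splits can give, and E3 was the only interaction with calls. Such splits cannot tell a genotype effect from a bias that falls along the groups. Without any single one of 8 libraries (named in the next part) 0 were called, in fits where the 202 genes kept their direction. Transcript length is argued against as the whole cause: with its trend taken out, 304 genes were called, 196 of the 202 among them. The called genes did differ in length, with medians of 4400 bases for higher and 3370 for lower estimates. That difference of 1030 lay outside the -626 to 682 of random sets. GC content is consistent with a large part of the pattern: with its trend taken out, 0 genes were called, the median absolute log2 of the 202 went from 0.775 (median SE 0.157) to 0.491 (0.145), 63.4% of its size, and the calls ended because effects shrank more than their errors. The GC medians of genes with higher and lower estimates differed by 14.5 points, against -2.91 to 2.71 in 1000 random sets, although this was specified after the names of the called genes had been read. All 202 kept their direction, which was likely for genes picked from these same libraries. A knockout effect that depends on feeding stays open, untested apart from the GC trend. Leaving out the 3 libraries with choroid plexus transcripts also ended the calls, with a median absolute log2 of 0.75 (SE 0.185). The 202 genes were picked in a fit that held the remaining libraries too. That fit therefore cannot tell whether choroid plexus tissue contributed.

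In fasted E4 knockout 1, 10 genes took the largest shares of 5517552 counts, with Cdk8 at 87060 CPM (115 or less in the other 6 fasted E4 libraries), D130009I18Rik at 76450, Sspn at 65260, Arhgap21 at 52950 and Lars2 at 32770. An effect of the knockout is argued against, since 1 of the 10 genes was higher in both other fasted knockouts than in all 4 wild types. A candidate explanation is reads of ribosomal RNA counted in genes that share its sequence; 0 of the 10 genes share a stretch of 25 bases with the 4 annotated models found, against 1 of 55337 genes in all. Those models hold 7100 bases, only part of the ribosomal unit, so this stays open; that requirement was added after the result, and an earlier test by the models' own counts was void because the table gives them no values. No biological explanation beyond the knockout was tested.

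In fasted E2 wild types, pituitary transcripts summed to 1288, 11730 and 5833 CPM, against 19.9, 19.5 and 41.6 in the knockouts. Of 10 measured pituitary genes 10 were higher in wild types, 9 of them without overlap (chance gives 10% for 3 against 3), which is consistent with pituitary tissue in the dissected samples. Gh and Prl led, at up to 5930 and 5630 CPM, and similar transcripts stood in libraries of both genotypes elsewhere: 6441 in fasted E4 knockout 3, 18930 in fasted E5 knockout 3 and 4551 in fasted E5 wild type 3. An effect of the knockout stays open: 2 of 2 measured genes were also lower in fed knockouts, but a minimum of 5 genes was set after that was seen, and so few genes decide little (Tbx19 was at -0.03, SE 0.35).

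In 12 groups of 4 libraries, with 12 measures each, 15 of 144 tests found a library far from the others by Dixon's criterion, where chance gives about 1 in 20. Fto was at 388.1 scaled CPM in fed E4 wild type 4 (others 342 to 349.5) and Irx5 at 3.043 in fasted E5 knockout 4 (others 3.262 to 3.27). Irx6 was at 0.4588 in fed E1 wild type 3 (others 1.202 to 1.306) and at 0.3422 in fed E4 wild type 4 (others 0.8781 to 0.9663). Summed pituitary CPM stood apart in fed E2 knockout 1 (60.51, others 6.818 to 11.17), fasted E4 wild type 4 (211.3, others 17.47 to 45.14), fasted E5 knockout 3 (18930, others 13.82 to 119.2), fasted E5 wild type 3 (4551, others 3.358 to 194.6) and fed E5 wild type 4 (33.42, others 12.73 to 14.39). Choroid plexus transcripts were at 3360 in fasted E5 wild type 1 (others 93.29 to 105.5). The fat list was at 12490 in fed E2 knockout 3 (others 15.51 to 27.47) and 28.34 in fed E4 wild type 1 (others 16.04 to 17.66). Liver transcripts were at 6.003 in fed E2 knockout 3 (others 1.375 to 1.606) and 52.62 in fasted E5 knockout 2 (others 1.457 to 5.332), and skeletal muscle at 376.1 in fed E1 wild type 2 (others 14.26 to 20.23).

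Other splits of the same libraries gave at least as many called genes, with real counts of 0, in all 35 splits of each 4-library comparison: the highest other count was 1 in fed E1, 2 in fasted E1, 89 in fed E2, 0 in fed E4, 6 in fasted E4, 541 in fed E5 and 1604 in fasted E5. For fasted E2 and fed and fasted E3, 10 of 10 splits gave at least the real 0 (highest other 0, 7 and 4). Any split matches a real count of 0, here and for the interactions and locus genes below. These shares therefore cannot decide on chance. In fed E2 and fed E5 a single split called any gene, and in fasted E5 2 splits did; such counts point to a structure of those samples other than genotype, which was not tested. Interactions with a real count of 0 were matched by 100 of 100 splits, with highest other counts of 6 in E1, 1 in E2, 4 in E4 and 3162 in E5; the locus genes, over both feeding states, likewise by 100 of 100, the highest other being 0 in E1 to E4 and 15 in E5. For fasting, 2 of 100 splits reached 1637, the real one and one with 2557 that exchanged fasted E1 wild type 3 with fed E1 wild type 1. This share is under 0.05, so chance is unlikely but not excluded. The larger count points to a structure of the E1 samples, which was not tested.

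For the gene lists by camera, chance could not be excluded where it could be assessed. As many lists as the real split were reached in 4 of 35 splits in fed E1 (real 15, highest other 18), 6 of 35 in fasted E1 (17, 18), 13 in fed E2 (14, 17), 30 in fed E4 (12, 20), 18 in fasted E4 (12, 16), 25 in fed E5 (9, 18) and 17 in fasted E5 (12, 16). In the fasting comparison 95 of 100 splits reached the real 7 (highest other 19). With 10 splits each, too few for a share under 0.05, fasted E2 gave 1 (17, 14), fed E3 6 (11, 16) and fasted E3 4 (13, 16).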

How the results depend on the processing

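The edgeR likelihood ratio test, fits without libraries holding other tissues, common genes, the E3 interaction's replicate block and the GC and length trends were chosen after the data had been seen; the cause of the differences below was not tested unless given.

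Genotype counts of 0 in edgeR stayed 0 with RLE normalization, and in E2, E4 and E5, where it was run, with genes common to all count tables; fasted E5 stayed at 0 without its 3 libraries with pituitary or choroid plexus transcripts. DESeq2 called 2 in fasted E1, 104 in fasted E2, 107 in fed E3, 527 in fasted E3, 4 in fed E4, 18 in fasted E4, 1 in fed E5 and 17 in fasted E5. The likelihood ratio test, which takes no account of the uncertainty of each gene's dispersion, called 5 in fed E1, 2 in fasted E1, 78 in fasted E2, 131 in fed E3, 280 in fasted E3, 2 in fed E4, 59 in fasted E4, 2 in fed E5, 9 in fasted E5 and 0 in fed E2. With both feeding states in one model fasted E2 gave 4 and fasted E3 605; with no filter on low counts fed E3 gave 1 and fasted E4 169; with a replicate block fed E3 gave 1. Leaving out each library gave 0 to 1 in fed E1 (1 without wild type 2) and fed E3 (1 without knockout 3), 0 to 772 in fasted E2 (772 without wild type 3, 71 without wild type 1), 0 to 23 in fasted E4 (23 without knockout 3, 1 without knockout 2) and 0 in the other 6.

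For fasting, E1 alone gave 784 genes, E3 alone 2891 and the knockouts of both lines 3007; leaving out each library gave 668 (without fed E3 wild type 3) to 3217 (without fasted E1 wild type 3), with 673 without fed E3 wild type 2, 748 without fasted E1 wild type 1, 956 and 1002 without fed E1 wild types 3 and 2, and 974 and 1048 without fasted E3 wild types 1 and 3. Over the 13 fits that left out 1 library, the 31 named genes kept their direction in 403 of 403 values and stayed called in 327, and 19 of them stayed called in every such fit. Over the other settings together with the fits of lowest and highest estimate, 220 of 278 values kept their direction and side of the threshold, 56 fell short of it, and 2 reversed, both in the fit of the knockouts of E1 and E3 together: Epyc at -0.378 and Cnr1 at -0.156.

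The E3 interaction gave 1104 genes by DESeq2, 0 without the 3 libraries with choroid plexus transcripts (fewer samples, with the median absolute log2 of the 202 genes at 0.75 and SE 0.185, against 0.775 and 0.157), 12 with a replicate block, 0 with the GC trend taken out and 304 with the length trend taken out. Leaving out each library gave 0 to 697 (697 without fasted wild type 2, 29 without fasted knockout 3, and 0 without fasted wild type 1 or 3, fasted knockout 2, fed wild type 2 or 3, or any fed knockout). DESeq2 gave 22 for E2, 2 for E4 and 2 for E5. Leaving out each library gave 0 to 28 in E2 (fasted wild type 1), 0 to 1 in E4 (fasted knockout 2) and 0 in E1 and E5. Over the 12 fits that left out 1 library the 5 named genes kept their direction in 60 of 60 values and stayed called in 20. Over the other settings together with the fits of lowest and highest estimate, 12 of 35 values fell short of the threshold and 23 stayed past it. For the locus genes over both feeding states every count was 0, also without each library, and 125 of 125 single values kept their side; in genotype comparisons all 402 values of Fto, Rpgrip1l, Irx3, Irx5 and Irx6 did so, over the settings and the fits of lowest and highest estimate, and 16 of them moved in estimate by more than the SE. The other genes named for genotype were not followed over the settings, and DESeq2 called several of them, as given with each element.

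Of 361 list tests in 11 comparisons, 139 passed camera with the preset correlation, 0 with an estimated one and 4 by fry, all 4 in the fasting comparison (glucocorticoid targets, low temperature, ribosomal proteins, blood). The median log2 of all genes lay between -0.03 and 0.02 under both TMM and RLE; the medians of 7 list tests near 0 differed in sign between them. Sex as a covariate was not run, since by Ddx3y it coincides with the element. The 95% intervals of Irx6, a low gene of the locus, span more than 1 log2 unit in each of the 10 genotype comparisons, in the deeply sequenced E2 libraries (-1.23 to 0.48 fed) as in E1 (-0.61 to 0.76 fed), so depth was not shown to set them; they cover replicate and counting error.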

Other observations

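The tests of fasting within each knockout group and within E2, E4 and E5, and the genes named in this part, were chosen after the data had been seen.

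In knockouts, fasted against fed, Npy was higher by log2 1.15 in E1 (SE 0.30), 2.91 in E2 (SE 0.40), 0.67 in E3 (SE 0.16; edgeR adjusted p 0.13), 1.30 in E4 (SE 0.42) and 1.91 in E5 (SE 0.35), passing the test in all but E3. In E3 the difference from wild types was -0.80 (adjusted p 0.141) and did not pass. In E2, E4 and E5 feeding coincided with the batch. Pomc in knockouts was at -1.55 (SE 0.24; edgeR adjusted p 0.000834) in E1, -1.12 (SE 0.41; 0.194) in E2, 0.08 (SE 0.32; 0.943) in E3, 3.86 (SE 1.11; 0.0277) in E4 and 4.06 (SE 1.35; 0.0378) in E5. In the last 2 groups, fasted E4 knockout 3 and fasted E5 knockout 3 held pituitary transcripts, at 6441 and 18930 summed CPM. Agrp was at -0.26 in E2, -0.48 (edgeR adjusted p 0.0171) in E4 and -0.71 (0.000492) in E5 wild types. In knockouts of these lines it was at -0.58, 0.06 and -0.42 (0.0199 in E5). Fto was at 0.02, -0.17 and -0.32 (0.0131 in E5) in these wild types and at -0.04, 0.08 and -0.23 in the knockouts. Those values of Agrp and Fto without an adjusted p did not pass.

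Between fasted and fed libraries of one element and genotype, edgeR called 5169 genes in E1 knockouts and 74 in E3 knockouts. The fasted E1 knockouts also held more thalamus transcripts than the fed ones, as given above. Where feeding coincided with the batch edgeR called 793 in E2 wild types and 214 in knockouts, 7334 and 4352 in E4, and 10214 and 6379 in E5.

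The tables deposited by the authors held protein-coding genes, with log2 fold changes that correlated at 0.998 to 1 with those here. At an adjusted p under 0.05 they listed 12 genes in fed E1 (0 higher in knockouts, 12 lower), 2 in fasted E1 (2, 0), 6 in fed E2 (6, 0), 39 in fed E3 (15, 24), 9 in fasted E3 (1, 8), 1 in fed E4 (0, 1), 43 in fasted E4 (38, 5) and 5 in fed E5 (2, 3); the edgeR quasi-likelihood test here called 0 in each. With the sign turned to knockout over wild type, the fed E1 genes included Myh1 (-6.54), Tnni2 (-5.88) and Ckm (-4.57), the fed E2 genes Adipoq (13.15), Fabp4 (12.94) and Car3 (11.16), and the fed E5 genes Prl (-9.03) and Gh (-8.54). Fto, Irx3, Irx5, Irx6 and Rpgrip1l were at an adjusted p of 1 in all 8 tables. How the authors adjusted their p values was not established here. Their adjusted p, also for these locus genes, need not be comparable with the Benjamini-Hochberg one used here. By the authors' q value under 0.05 the counts were larger in each table. They were 43 in fed E1, 6 in fasted E1, 138 in fed E2 and 255 in fed E3. The other tables gave 400 in fasted E3, 4 in fed E4, 246 in fasted E4 and 9 in fed E5. Tables for fasted E2 and fasted E5 were not used here.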
